A study of Mus musculus with 5 samples.

How the data were processed

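Messenger RNA levels in adult retina of C57/B6 mice were set against those in cortex of Swiss-Webster mice on postnatal day 1. The total RNA came from 2 pools, 1 per tissue, and was hybridised to 5 two-colour Agilent arrays. Per the labels, retina RNA carried the red dye Cy5 and the cortex reference the green dye Cy3 on every array, so no dye swap was made. The labels call the arrays technical replicates. They form 1 group here, with 1 pool per tissue, and tissue, age, strain and dye all change together. The p-values of the limma tests therefore measure labelling and hybridisation error between arrays of the same pools. They compare the 2 pools and say nothing of the spread between animals, for which there was no replicate.

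The deposited value table holds 1 column per array and 21446 probes, with signed values that were read as log10 ratios. The base is likely and not stated in the sources used here: the values stop exactly at 2 and -2, where 5 values lie, as Agilent's log10 ratios do. The direction, retina over cortex, is likely from the order of the tissues in the titles and from the dyes. Background correction, dye normalization, scanner software and filters are not given in the sources used here. The median of the deposited log10 column was 0 on arrays 1 to 4 and -7.32e-05 on array 5, so the columns stand centred, by a method that is unknown. Spot intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

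Deposited values were multiplied by 3.32 to give log2 ratios. An exact 0, which occurred 174, 203, 214, 1068 and 406 times on arrays 1 to 5, was read as no value. Of the 21446 probes, 11813 had 1 gene symbol in the platform annotation, 559 had several and 9074 were not listed there. Symbols were matched by gene identifier to a RefSeq table of assembly GRCm38.p6, which named 11782 probes, while 31 had no match among the mouse genes. No coordinates are given, because the sources name no build for the array. A gene's value on an array was the mean over its probes with a value on all 5 arrays, which left 8798 genes from 11500 probes. Probes of the same gene disagreed in places: 2086 genes had several probes, the median range of their probe means was 0.38 log2, and in 850 of these genes the probes differed in sign.

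Each gene was tested with limma version 3.58.1 in R version 4.3.3, by an intercept fitted to the 5 log2 ratios with lmFit. The intercept was tested against 0 with eBayes, and against a minimum of 2-fold (a log2 ratio of 1) with treat, called the 2-fold test below. All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is called higher or lower in retina only where it passed the 2-fold test. The procedure was tested on simulated data for this comparison with 8798 genes. It recovered 89.6% of changed genes at a log2 size of 1.5, 98.5% at 2 and 98.5% at 3, with 0 false calls. Unchanged genes were simulated at a ratio of exactly 0, far from the 2-fold minimum, with independent noise. The 0 false calls were thus nearly fixed in advance and give no rate for real genes close to 2-fold.

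The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took genes that passed the 2-fold test with the same sign on all 5 arrays, and on all probes where several, and named the 8 highest and the 8 lowest. From each list it also named the 2 members farthest from 0 that passed, or the 1 member farthest from 0 where none passed. Further members are named as examples and were chosen after their values were seen. The lists cover rods, cones, photoreceptor transcription factors, bipolar cells, amacrine and horizontal cells, ganglion cells, the ribbon synapse, Müller glia and astrocytes, pigment epithelium, lens, muscle, red cells, meninges, microglia, vessels, oligodendrocytes, cortical projection neurons, cortical interneurons, immature neurons, the cell cycle, axon guidance, glycolysis, the respiratory chain, ribosomal proteins and sex-linked genes. The median log2 ratio of a list with at least 3 measured genes was ranked among 10000 random lists of the same size, matched on the SD between arrays in 10 strata. This percentile describes these pools and is no test.

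Repeatability was described by the SD of each gene over the arrays and by Pearson's r across genes for each pair of arrays. The position of a probe was inferred from its probe number, taken as 215 columns and 105 rows, the split of the probe numbers into equal rows that gave the highest correlation of residuals between rows. The residuals of adjacent probes were correlated, with 1000 permutations of the positions. Alternatives covered centring, scaling, the filter on missing values, the noise of genes, the probe rule (the mean against the median probe by ratio, the lower one of 2), the prior, array weights, the minimum fold, the log base and each array left out. The sex make-up of the pools was tested in 3 ways in turn, all chosen after the results were seen: by the signs of Xist and Eif2s3y, which left it open, by the median of the lower X-linked calls, dropped because calling at 2-fold nearly fixes it, and by the shift of all X-linked genes, which is reported. The last way left it open too, because that shift was too small to change the calls much. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.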

Results

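Adult mouse retina was compared with mouse cortex of postnatal day 1 on 5 arrays, each of which carried both pools of RNA. The series was made to learn how much expression values vary within an array platform, and the same pair of pools was run on every array. The values below are log2 ratios of the retina pool over the cortex pool, given as mean ± SD over n = 5 arrays. Log base and direction are likely rather than stated, and a gene's fold depends on the base. Were the direction the other way, every sign and every higher or lower below would turn, with sizes, total counts and tests as they are. The fixed lists argue against that. With the signs turned, 2 of 2 measured rod genes and the 1 measured cone gene would be higher in newborn cortex. In retina, 8 of 18 transcription factors of cortical projection neurons would be higher and 0 lower. Used in this way, these lists are no independent result.

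Photoreceptor and glycolysis genes were often higher in the retina pool than in the cortex pool, and genes of growing neurons were mostly lower. The highest ratio was that of Cdhr1, a cadherin of the photoreceptor outer segment, at 4.30 ± 0.05 or 19.7-fold higher in retina. The lowest was that of Mpped1, a metallophosphoesterase, at -4.35 ± 0.12 or 20.4-fold lower. Dcx, a microtubule-binding protein of migrating neurons, stood at -3.99 ± 0.04 or 15.9-fold lower. Of 8798 genes, 583 passed the 2-fold test, 246 higher and 337 lower in retina, and all 583 had the same sign on all 5 arrays.

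Besides Cdhr1, the 8 highest genes included the carbonic anhydrase Car2 at 4.14 ± 0.07 and the hexokinase Hk2 at 3.80 ± 0.17. The potassium channel Kcnj14 reached 3.74 ± 0.05 and the acyltransferase Agpat3 3.58 ± 0.09. The heparan sulfate sulfotransferase Hs3st3b1 stood at 3.51 ± 0.12, the homeobox factor Otx2 at 3.42 ± 0.03 and the anion transporter Slco4a1 at 3.41 ± 0.11. Among the 8 lowest were Fnbp1l, a Cdc42-binding protein that promotes actin assembly, at -3.87 ± 0.05, and the neuropeptide gene Nts at -3.69 ± 0.06. The Rac exchange factor Tiam2 stood at -3.61 ± 0.09 and the long noncoding RNA Pantr1 at -3.44 ± 0.09. The phosphatase inhibitor Ppp1r14b was at -3.42 ± 0.03 and the actin-binding protein Enc1 at -3.33 ± 0.10. A second Hs3st3b1 probe, with no value on array 4, read 0.18 ± 0.29 on the other 4 arrays, and without array 4, where both probes count, the gene stood at 1.83 and would not be among the 8 highest. The adjusted p of the limma 2-fold test among these 16 genes was highest for Hk2, at 5.23e-07.

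**Figure D1:**
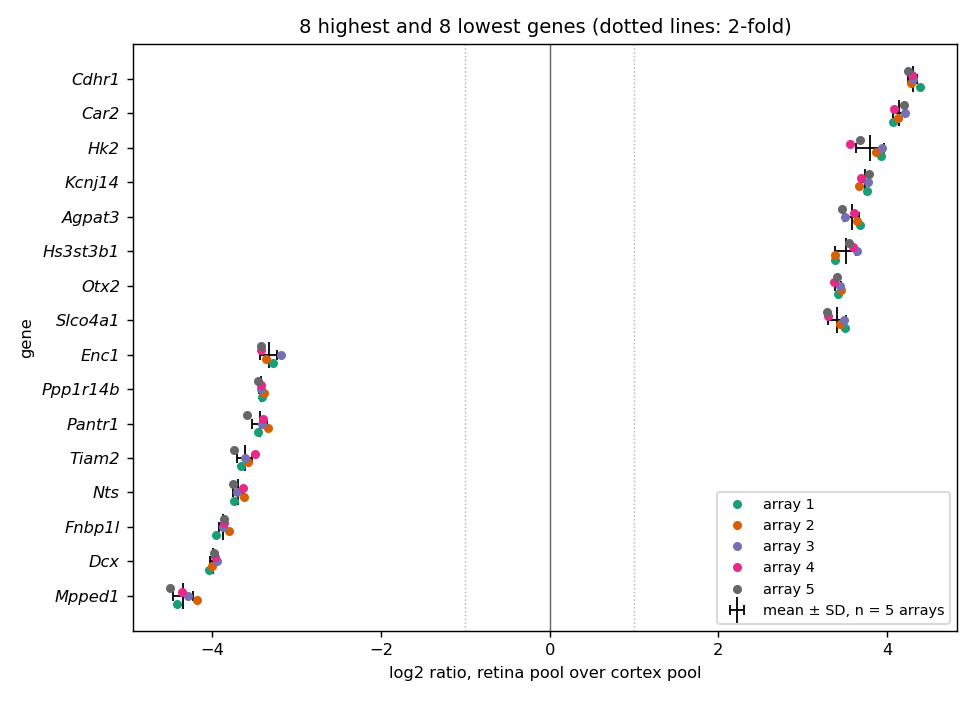
Log2 ratios (retina pool over cortex pool, horizontal axis) of the 8 highest and 8 lowest genes, with a point for each of the 5 arrays and a bar for mean ± SD. The points of each gene lie close together and far outside the dotted 2-fold lines, from Cdhr1 at 4.30 to Mpped1 at -4.35.

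Most of the measured photoreceptor genes were higher in retina. A gene counts as measured where a probe annotated with its symbol had a value on every array. The annotation did not list 9074 of the 21446 probes. An unmeasured gene may therefore still have a probe on the array, which was not tested. Of 34 rod phototransduction and outer segment genes on the list only 2 were measured, and both were higher: Cdhr1 and the rod channel subunit Cngb1, at 2.97 ± 0.23. The single measured cone gene, the short-wave opsin Opn1sw, stood at 3.28 ± 0.09, or 9.72-fold higher. Of 6 photoreceptor transcription factors, 4 were higher, among them Otx2, Esrrb at 3.31 ± 0.09 and Neurod1 at 2.78 ± 0.33, while Rxrg (-0.29 ± 0.17) and Bhlhe40 (0.41 ± 0.26) did not pass. A second Esrrb probe, with no value on array 4, read 0.29 ± 0.18 on the other 4 arrays, and without array 4, where both probes count, Esrrb stood at 1.78. In the ribbon synapse list 2 of 3 genes were higher, Stx3 at 2.58 ± 0.11 and Ctbp2, the gene of the ribbon protein RIBEYE, at 1.83 ± 0.05, while Rab3a (0.65 ± 0.03) did not pass. The probes of Stx3 lay 2.22 log2 apart, both above 0, and with the lower one alone it stood at 1.47. The counts adjusted over the list alone were the same for these 4 lists.

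Markers of other retinal neurons were partly higher. Of 3 bipolar cell genes, 1 was higher, the G protein subunit Gng13 at 3.37 ± 0.08. Of 10 amacrine and horizontal cell genes, 4 were higher, led by the homeobox factor Pax6 at 2.99 ± 0.03 and the septin Septin4 at 2.33 ± 0.05, and 6 did not pass. Of 4 ganglion cell genes, 2 were higher, the synuclein Sncg at 1.87 ± 0.09 and the neurofilament gene Nefl at 1.26 ± 0.06. With the lower of its 2 probes in place of their mean, Nefl fell below the test, at 1.01 with an adjusted p of 1 from limma. In the Müller glia and astrocyte list 4 of 10 genes were higher, including the secreted Dkk3 at 2.69 ± 0.08 and clusterin, Clu, at 2.18 ± 0.15, with array 5 apart at 2.44. The connexin gene Gja1 was lower, at -1.48 ± 0.14, with probes 1.94 log2 apart. The counts adjusted over the list alone equalled those over all genes in these 4 lists.

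Many glycolysis genes were higher in retina. Of 16 measured, 9 were higher, none was lower and 7 did not pass, with 10 higher when adjusted over the list alone. Their median was 1.33, at the 100th percentile of random lists. Hk2 led, followed by pyruvate kinase Pkm at 2.22 ± 0.05, lactate dehydrogenase Ldha at 1.97 ± 0.04 and aldolase Aldoa at 1.85 ± 0.07. The glycolytic Pfkl (0.17 ± 0.09) and Pfkp (0.14 ± 0.18) did not pass. In contrast, 0 of 25 respiratory chain genes passed the limma 2-fold test, whether adjusted over all genes, over the list alone or not at all. The farthest from 0 of these was the succinate dehydrogenase subunit Sdha, at 0.87 ± 0.08. Of 47 cytosolic ribosomal protein genes, 2 were lower, Rpl10 at -1.36 ± 0.16, with array 1 apart at -1.65, and Rpl15 at -1.29 ± 0.06, and the list median was -0.41, below all random lists. The 2 lower ribosomal genes also passed when adjusted over the list alone.

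Genes of immature neurons were the group with the most lower genes. Of 23 measured genes of neurite outgrowth and immature neurons, 19 were lower and none was higher, with the same count adjusted over the list alone. The list median was -2.01, below all random lists. Dcx was followed by the growth cone protein Gap43 at -3.19 ± 0.13, the tubulin Tubb2b at -2.91 ± 0.09 and the transcription factor Sox11 at -2.90 ± 0.06. The probes of Dcx lay 1.23 log2 apart, with the lower one at -4.61, and those of Sox11 2.98, all on the lower side. Sox4 (-0.88 ± 0.04) and Nnat (-0.19 ± 0.12) were among the 4 that did not pass.

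Transcription factors of cortical projection neurons were lower for 8 of 18 genes, with 10 not passed and none higher. The HLH inhibitor Id2 stood at -2.86 ± 0.08, the nuclear receptor Nr2f1 at -2.71 ± 0.08 and Neurod6 at -2.69 ± 0.09. The median of the list was -1.04, below all random lists. Of 7 cortical interneuron genes, 1 was lower, the homeobox factor Dlx1 at -2.82 ± 0.05. The GABA-synthesizing enzyme gene Gad1 (0.99 ± 0.11) did not pass. In the axon guidance list 5 of 17 genes were lower, led by the semaphorin receptor Nrp1 at -2.06 ± 0.14 and the Slit receptor Robo1 at -1.87 ± 0.11, with array 1 apart at -2.06. Of 33 cell cycle genes, 5 were lower, among them the replication helicase subunit Mcm6 at -1.82 ± 0.07 and the ribonucleotide reductase subunit Rrm2 at -1.80 ± 0.12. The other 28 cell cycle genes did not pass, and Mcm2, of the same helicase, stood at 0.83 ± 0.11. All counts in these 4 lists were the same adjusted over the list alone.

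**Figure D2:**
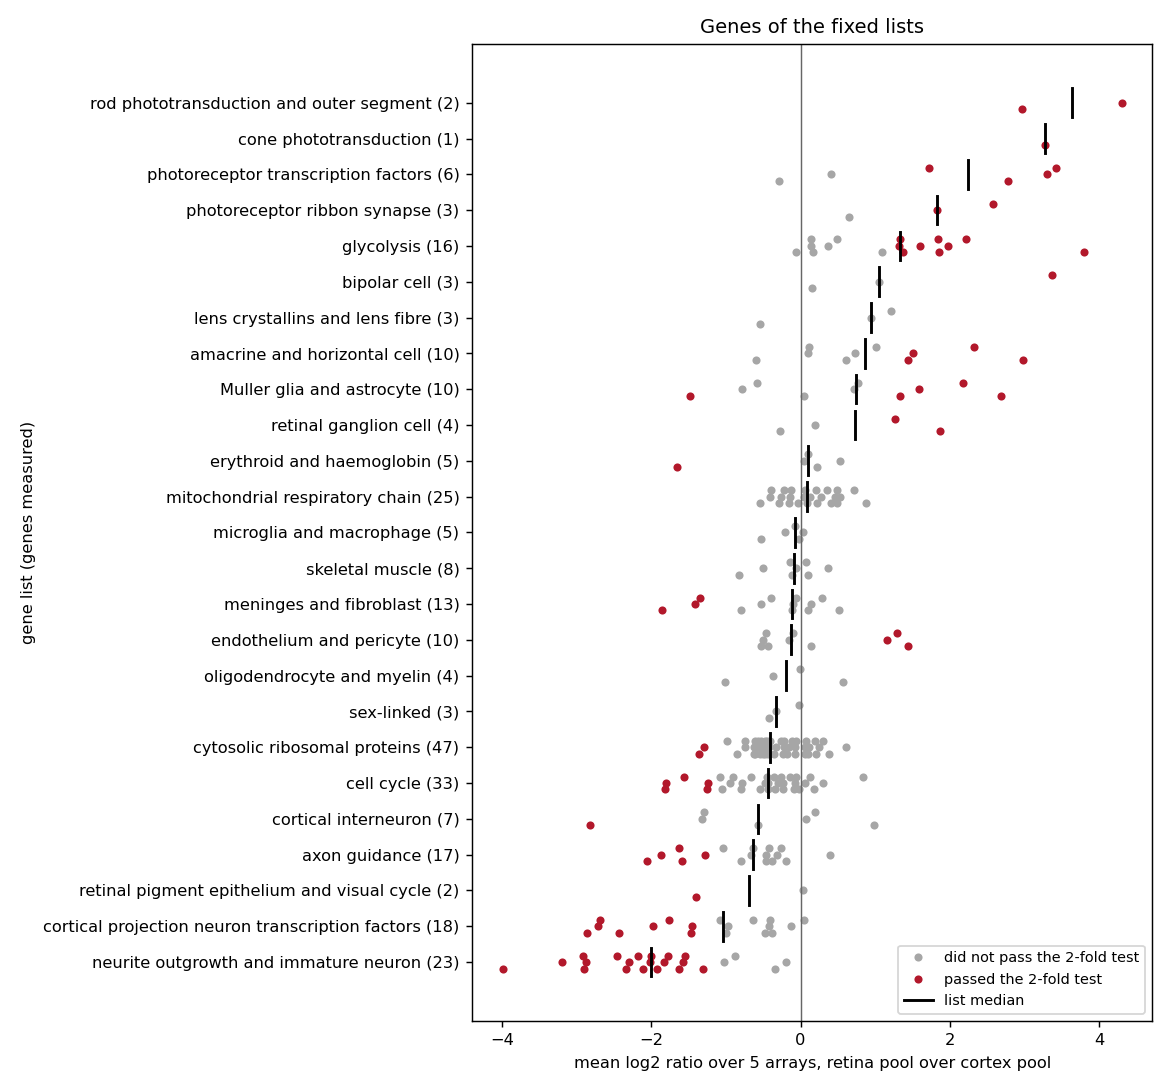
Mean log2 ratio over 5 arrays (retina pool over cortex pool, horizontal axis) of each measured gene in the 25 fixed lists, 1 point per gene, red where the gene passed the 2-fold test and grey where it did not, with a black line at the list median. The lists run from rod genes, with a median of 3.64 over 2 genes, down to genes of immature neurons, with a median of -2.01 over 23 genes.

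In 8 lists for other cell types that the tissue pieces could hold, 8 of 50 genes passed the 2-fold test, or 16.0%, against 6.63% of all genes. In the meninges and fibroblast list 3 of 13 genes were lower in retina, Postn at -1.86 ± 0.27, Igfbp2 at -1.41 ± 0.04 and Dcn at -1.35 ± 0.21. Of 5 red cell genes, 1 was lower, the adult globin Hbb-b2 at -1.66 ± 0.07. The median of that list was 0.10 and its mean -0.15, so they differ in sign. The pigment epithelium list had 2 measured genes, of which the transthyretin gene Ttr was lower at -1.40 ± 0.04. In the vessel list 3 of 10 genes were higher, including the VEGF receptor Flt1 at 1.44 ± 0.08 and the glucose transporter Slc2a1 at 1.29 ± 0.09. The 2 probes of Slc2a1 lay 2.48 log2 apart, and with the lower one alone it stood at 0.05 and did not pass, with an adjusted p of 1 from limma. The vessel list's median was -0.12 and its mean 0.18, which differ in sign too.

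No gene passed limma's 2-fold test in 4 of these 8 lists (lens, muscle, microglia and oligodendrocytes) or in the sex-linked list, and of their genes only Crygb reached an unadjusted p below 0.05. Those farthest from 0 were Crygb, of 3 lens genes, at 1.22 ± 0.24, Mylpf, of 8 muscle genes, at -0.83 ± 0.45, C1qc, of 5 microglia genes, at -0.52 ± 0.10, Olig1, of 4 oligodendrocyte genes, at -1.01 ± 0.07, and Xist, of 3 sex-linked genes, at -0.43 ± 0.05. The 5 probes of Xist differed in sign, with means from -0.90 to 0.12 log2 and 4 of them below 0. Counts adjusted over the list alone were the same as those over all genes in the 8 lists and the sex-linked list.

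The list medians outside the central 95% of random lists numbered 14. Higher medians were those of photoreceptor transcription factors (2.25), the ribbon synapse (1.83), glycolysis, bipolar cells (1.06), lens (0.94), amacrine and horizontal cells (0.87), Müller glia and astrocytes (0.74) and ganglion cells (0.72). Lower medians were those of immature neurons, cortical projection neurons, axon guidance (-0.63), cortical interneurons (-0.58), the cell cycle (-0.43) and ribosomal proteins. The medians of meninges (-0.11), microglia (-0.07), muscle (-0.09), oligodendrocyte (-0.19), respiratory chain (0.09) and sex-linked genes (-0.33) lay within the central 95%, as did those of the red cell and vessel lists.

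The arrays repeated closely, which was the question of the design. The SD between arrays had a median of 0.085 log2 over 8798 genes, a factor of 1.06, and a 95th percentile of 0.354. Pearson's r across genes ran from 0.878 to 0.956 over the 10 pairs of arrays, with a median of 0.923. Genes are not independent replicates, so no p is given for it. The sign was the same on all 5 arrays for 73.5% of genes, where chance alone gives 6.25%. Against a ratio of 0, limma called 6481 genes, 3256 with a mean log2 ratio above 0 and 3225 with one below 0. That count shows how small a ratio the repeats resolve, and not how many genes differ between the tissues. Retina carried Cy5 on every array, so a dye or probe effect of a gene would repeat. Such effects could enter this count and the share of genes with the same sign.

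Fewer arrays gave fewer calls of the 2-fold test. The 10 subsets of 2 arrays gave a median of 383 genes, those of 3 arrays 498.5 and the 5 subsets of 4 arrays 553. Of genes called from 3 arrays, a median of 99.4% were also at least 2-fold from 0, with the same sign, on the mean of the arrays left out. A mean of at least 2-fold with no test was reached by 850 genes, 356 above 0 and 494 below 0. The SD of 22 genes exceeded 1 log2.

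Neighbouring probes had correlated residuals from their means over the arrays, with r of 0.322, 0.449, 0.304, 0.289 and 0.236 on arrays 1 to 5. The residuals of a probe cancel out over the 5 arrays, so a pattern on 1 array enters the others with the opposite sign. The 5 correlations are therefore not separate findings. The permutation p was 0.001 on each array, the smallest that 1000 permutations can give. The layout of rows was itself chosen by the correlation of these residuals. The permutations did not repeat that choice, so the p does not allow for it. Medians in blocks of 15 by 15 positions ran from -0.56 to 0.08 log2 on array 2, the widest range of the 5 arrays. In the block where array 2 read -0.56, arrays 1, 3, 4 and 5 read 0.14, 0.18, 0.03 and 0.17.

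**Figure D3:**
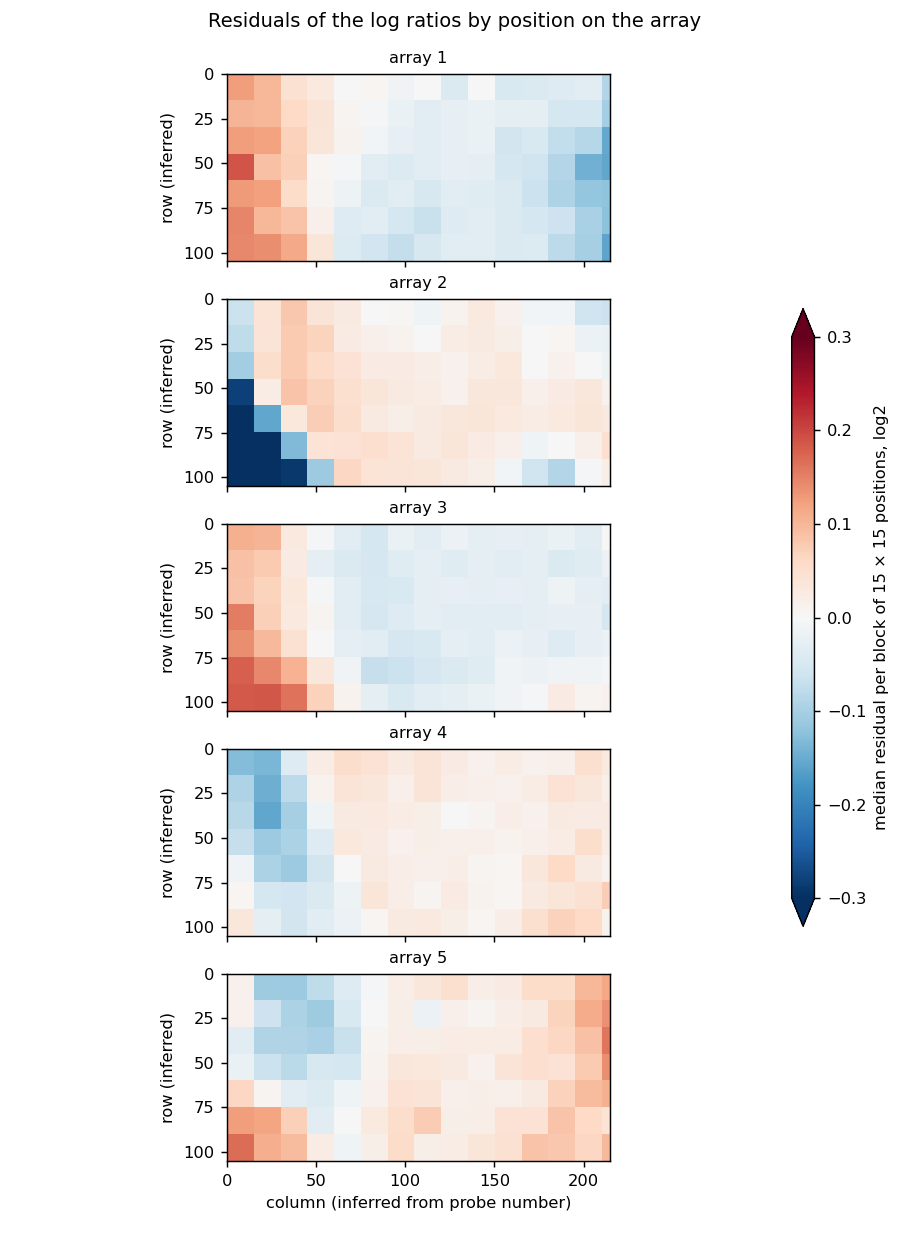
Median residual of the log2 ratio in blocks of 15 by 15 positions (colour, log2) against inferred column and row, 1 panel per array. A corner of array 2 reaches -0.56, and on array 1 the residuals run from 0.19 on the left to -0.16 on the right.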

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

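The tests of the regular spacing were chosen after the results were seen.

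Array 4 held 1068 exact 0 values, while the other arrays held between 174 and 406. Of those 1068 values, 1 lay in the leftmost 30 columns of inferred positions, which hold 3000 probes, and 77.8% lay in the right-hand part. At probes that were also 0 on array 4 lay 117 of the 174 exact 0 values of array 1, 196 of 203 on array 2, 187 of 214 on array 3 and 380 of 406 on array 5. On array 1, 39 lay in the leftmost 30 columns and 46.0% in the right-hand part.

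Clusterin, Clu, read 2.44 on array 5 and between 2.07 and 2.14 on the other arrays. The axon guidance receptor Robo1 read -2.06 on array 1 and between -1.85 and -1.79 elsewhere, and the ribosomal gene Rpl10 read -1.65 on array 1 and between -1.32 and -1.25 elsewhere. The signs of the 3 genes were the same on all arrays. Among 56 measures checked for an array far from the rest, 4 were found, and chance gives about 5% of them.

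Probes without a single mouse gene symbol, which entered no comparison, gave 761 passes of the limma 2-fold test. Of these, 660 were lower and 101 higher in retina, or 86.7% lower, against 58.8% lower among 776 passes of named probes. A candidate explanation is a set of repeated features printed at regular spacing. Of the 660 lower probes, 66.2% had lower probes at the same distance of 4, 7 or 8 probe numbers on both sides, where 1000 random placements gave at most 1.21%, and their median ratio was -3.35, or 10.2-fold lower. Without the 13 inferred rows that hold such runs, 66.8% of the passes were lower (95% exact binomial interval 60.8% to 72.4%, against 55.2% to 62.3% for named probes). The intervals overlap and take probes as independent, so whether an excess remains is open, and no biological explanation was tested.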

How the results depend on the processing

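The position correction, the reading of exact 0 as 0 and the fit without arrays 1 and 4 (most values at the limit of the scale, most exact 0 values) were chosen after seeing the data, as was leaving out arrays for the list medians. Leaving out 1 array at a time gave 528 to 562 genes past the 2-fold test and 5934 to 6256 against 0. The median SD between arrays was then 0.0737 to 0.0860, lowest without array 5. Without arrays 1 and 4, 466 genes passed, 460 of them among the 583. That fit counted 8 glycolysis, 4 cell cycle, 2 vessel and 2 meninges genes, in place of 9, 5, 3 and 3. A minimum of 1.5-fold gave 1408 genes and one of 4-fold 105, which follows from the minimum itself. Reading the deposited values as log2 left 7 genes past the 2-fold test, since each ratio is then smaller, so this count rests on the log base. Spearman's rho had a median of 0.892 over the pairs of arrays, and Pearson's r over genes within 2-fold of 0 a median of 0.821, where little of the spread of the ratios remains. The other 61 alternative values of the counts, SDs and correlations stayed within 1.5 times the reported count or within the spread between pairs of arrays. Of the named gene results, 508 kept their side of the 2-fold test and their sign and 2 fell below it, Nefl and Slc2a1 with the median probe, which is the lower one where a gene has 2. The fold moved by over 1.5 times in 9 of these values, from 5 genes. Hs3st3b1 and Esrrb, at 3.51 and 3.31, read 1.83 and 1.78 without array 4, 1.89 and 1.79 without arrays 1 and 4, and 1.82 and 1.77 with exact 0 kept as 0, since a second probe of each, with no value on array 4, then enters the mean. With the lower of 2 probes Dcx read -4.61, Stx3 1.47 and Slc2a1 0.05. All 220 list medians stayed inside or outside the central 95% of random lists as before. Subtracting the median residual of neighbours left 602 genes past the 2-fold test, 574 of them among the 583. No paired analysis was possible because the arrays form 1 group. Signal over background is unknown, so weak spots could not be set apart.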

Other observations

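Further gene groups were listed after the data were seen, so their counts are no independent evidence of direction. Of 13 sterol synthesis genes, 2 were lower and none was higher, with the same count adjusted over the list alone: Hmgcs1 at -2.40 ± 0.16 (SD, n = 5 arrays) and squalene epoxidase Sqle at -1.66 ± 0.15. Of 21 genes of fatty acid oxidation, 7 were higher in retina and none was lower. They included the mitochondrial Cpt2 at 1.67 ± 0.06 and Acadm at 1.61 ± 0.08, and the peroxisomal Amacr at 1.68 ± 0.09 and Phyh at 1.17 ± 0.05. Of 6 Bardet-Biedl cilium genes, 3 were higher: Bbs7 at 1.92 ± 0.22, Bbs2 at 1.66 ± 0.34 and Bbs4 at 1.36 ± 0.08. Of 12 circadian clock genes, 3 were higher, Nr1d2 at 2.00 ± 0.04, Rorb at 1.72 ± 0.11, which is also on the photoreceptor list, and Arntl at 1.38 ± 0.15. Counts adjusted over the list alone were the same for these 3 lists. Among the longest 10% of genes, those of at least 130 kb, 8.18% were lower and 2.50% higher in retina, and among the rest 3.35% were lower and 2.83% higher.

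The tests of the X chromosome and of genes placed side by side were chosen after the results were seen, and the test on regularly spaced probes after the pattern was seen. X-linked genes that passed the 2-fold test were mostly lower in retina, 29 lower against 3 higher (Pgk1, Hprt and Xiap), while autosomal genes gave 308 against 243. Fisher's exact test of the split gave an adjusted p of 0.0012 over 20 chromosomes, with genes as units, which are not independent of each other. Longer genes on the X chromosome are argued against as the cause, since the odds ratio within 10 strata of gene length was 7.75 (95% interval 2.28 to 26.3). The sex make-up of the pools stays open. The median of all 307 X-linked genes lay only 1.04-fold below that of autosomal genes, so a shift shared by all of them was small. With that difference taken out the split was 28 against 3, an odds ratio of 7.35 (95% interval 2.23 to 38.2). A difference that small could hardly move a call at 2-fold, so this split does not decide the question. An effect of sex on only some X-linked genes was not tested. Tissue, age and strain, which change together here, were not tested apart and remain open too.

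Residuals of neighbouring probes went together on all 5 arrays, and subtracting the median residual of the neighbours, with the probe itself left out, lowered the median SD of named probes by 11.3%, which gives the size of the pattern and does not test its cause. A signal that depends on position on each array was tested on the 437 regularly spaced probes, whose residuals should then follow those of the named probes around them. The correlations were 0.102, 0.279, -0.013, -0.030 and 0.080 on arrays 1 to 5, above the highest of 1000 permutations on array 2 only. The prediction was thus met on array 2 and not on the other arrays, which leaves the cause open there. The regularly spaced probes lie in only 13 inferred rows, and whether that hides a pattern on the other arrays was not tested. The test leaves the neighbour correlation of the named probes as it is. That correlation was found by inferred position on all 5 arrays, whose residuals are linked, so it does not count as 5 separate findings. Genes of like retina to cortex ratio placed side by side are argued against, because the mean log ratios of neighbours correlated at only 0.0198. Neighbours of like expression level were not tested, because spot intensities were not used, so that explanation stays open. The same pools were on every array, so the design gives no biological explanation to test.

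Turning the sign of the ratios on some of the arrays gives 16 assignments, the real one included. Only 1 assignment, the real one itself, gave 583 genes past the 2-fold test, and the highest of the others gave 0. The arrays repeat the same pools, so turning some of them pulls the means toward 0, and the low counts of the other assignments follow from the design. With 16 assignments the share also cannot fall below 0.0625, so chance is not judged from them.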
